A study of Gallus gallus with 12 samples.

How the data were processed

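Total RNA from 12 samples of White Leghorn embryos was measured on Affymetrix GeneChip Chicken Genome Arrays, 1 array per sample, from 5 µg of total RNA each. The samples fall into 4 groups of 3: blastoderm, CEF, GSC and PGC. The labels describe the replicates as independent samples and state no pairing. Each PGC or GSC sample pooled the gonads of 100 embryos, and each blastoderm or CEF sample came from 5 embryos. The antibody of the magnetic sort is not given in the sources used here.

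The authors deposited 1 table with 38535 probe sets and 1 column per array. The deposited values are on the log2 scale, from 1.02 to 13.18, as read from the values and from the steps between the hybridization spike-in controls. Array medians and upper quantiles were nearly equal, so the values had been scaled between arrays by the authors, and that scaling was kept. The labels name MAS5 with neither a version nor a role, and how the log2 values were made is not given in the sources used here. Raw intensity files were not used here.

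Control probe sets of the manufacturer (96) and probe sets for viral and reporter sequences (746) were left out of the tests, which left 37693. Of these, 27166 had 1 gene symbol in the array's annotation, 177 had several and 10350 had none. Of the probe sets with 1 symbol, 26851 carried a symbol found in the RefSeq annotation of the chicken genome. No coordinates are given, since the probe set sequences were not aligned. A gene was represented by its probe set with the highest mean over all 12 arrays, with probe sets ending in _x_at used only where a gene had no other, which gave 13050 genes. The level of 3.61, the 99th percentile of the viral and reporter probe sets, was taken as background, and 15389 probe sets (40.8%) had no group mean above it.

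Group means were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend over all 12 arrays (8 residual degrees of freedom), two-sided, and Benjamini-Hochberg adjustment over the 37693 probe sets of each comparison. A probe set was called at an adjusted p below 0.05. The 4 main comparisons were PGC versus blastoderm, PGC versus CEF, PGC versus GSC and GSC versus CEF. Probe sets that separate PGC, or PGC and blastoderm, from the other groups were those called in the same direction in each comparison involved. The 23 gene lists were tested with camera at a preset correlation of 0.01, with adjustment over all 92 tests, and a list needed at least 5 measured members. Beside each list stands the number of members called over all probe sets and the number adjusted over the list alone. No list call held when camera estimated the correlation from the data.

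Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 10 called genes with the largest log2 fold change in each direction that have an assigned symbol and no overlap between the arrays of the groups. It adds up to 3 called members of each list in each direction, and a set of genes always given: DDX4, DAZL, NANOG, POU5F3, KIT, CXCR4, PRDM14, SOX2, LIN28A, COL1A1, COL1A2, WT1, NR5A1, LHX9, GATA4, GAPDH and ACTB. For the sets that separate groups it takes the 10 genes with the largest of their smallest fold changes. Of older symbols in the annotation, 4 (for ALAS2, TIAL1, GADD45B and MYBPH) were not used to match list members because they belong to another gene, a decision made after the annotation was seen.

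RNA integrity was taken as the 3′ minus 5′ difference of the actin and GAPDH control probe sets and compared between groups by exact two-sided permutation tests, for which 3 against 3 arrays allow no p below 0.1. Array similarity is the Pearson correlation across probe sets, which are not independent replicates. The main fits did not pair samples by replicate number. Deviations from the group means in PGC and GSC arrays of 1 number correlated at 0.18, -0.07 and 0.00. The poly-A spike-in means, however, nearly matched by number between blastoderm (5.72, 4.63 and 4.15) and GSC (5.65, 4.65 and 4.18). Processing shared by replicate number is thus not excluded.

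The alternatives tried were offsets of 16 and 64 added on the linear scale before the logarithm, a filter on low values, quantile normalization, median centring, limma without the trend, with a robust prior and with array weights, a minimum change of 2-fold, a replicate block, only the 2 groups compared, and each array left out in turn. For gene lists they were an estimated correlation, fry, the mean over a gene's probe sets and all probe sets. The fits and the list test were checked on simulated data: with the arrays of PGC versus GSC and 50 genes changed per fold, 2 genes changed 1.5-fold were recovered, 28 changed 2-fold, 47 changed 4-fold and 49 changed 8-fold, and 7 unchanged probe sets were called. A shifted list was called in 3 of 3 comparisons and unshifted lists in 0 of 80 tests by camera. The simulated noise was independent between probe sets, so this check cannot show how often camera calls lists of correlated genes falsely. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision.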

Results

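Transcript levels were measured with Affymetrix chicken genome arrays in 12 RNA samples from White Leghorn embryos, 3 samples in each of 4 groups. PGC are primordial germ cells, the embryonic precursors of sperm and eggs. They were sorted magnetically from gonads of 6.5-day embryos, and GSC are the gonadal stromal cells, the somatic cells obtained by the same sort. Each PGC and each GSC sample pooled gonads of 100 embryos of both sexes, with 270000 PGC or 9000000 GSC per sample. CEF are embryonic fibroblasts from 5 embryos of 6.5 days per sample, grown in culture to passage 2, with the embryonic body as the source in the study design and the muscular area in the sample labels. Blastoderm samples hold dissociated cells of 5 freshly laid eggs each, before the germ layers form. Values are on the log2 scale, 1 array was run per sample, and the number of arrays limits the precision. The median value of an array lay between 3.50 and 3.65, and a level of 3.61, the 99th percentile of probe sets for viral and reporter sequences, served as the background. A log2 fold change is the first-named group minus the second, and its SE is that of the fitted model. Where the lower group lay within background the fold depends on the floor of the values, which is said beside each group of genes. An offset of 64 added before the logarithm moved the fold of 65 of 105 called named genes in PGC versus GSC by over 1.5 times, 90 of 123 in PGC versus blastoderm, 101 of 132 in PGC versus CEF and 80 of 114 in GSC versus CEF. An offset of 16 moved 41, 61, 83 and 69. Levels near the highest value on any array, 13.18, such as those of the globins in PGC and GSC, may be compressed.

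The arrays of one group resembled each other more than those of any other group, with correlations across probe sets between 0.972 and 0.994 within groups. Among the pairs of groups, GSC and PGC were closest, with a median correlation of 0.941, against 0.891 for PGC and blastoderm, 0.895 for GSC and CEF and 0.874 for PGC and CEF. Over probe sets whose highest group mean exceeded the median of all values, these were 0.883, 0.794, 0.799 and 0.761. PGC replicate 3 stood nearer to the mean of the GSC arrays (r = 0.963) than PGC replicates 1 (0.931) and 2 (0.940), and further from the other PGC arrays (0.974 against 0.981 and 0.982). The germ cell genes DDX4, DAZL and KIT were lowest in that array within the PGC group, and COL1A1 and NR5A1 were highest. The 3′ minus 5′ signal of the actin and GAPDH control probe sets, a sign of RNA integrity, was 0.23 ± 0.15 in PGC, 0.00 ± 0.08 in GSC, 0.34 ± 0.33 in CEF and 0.55 ± 0.23 in blastoderm (mean log2 ± SD, n = 3). PGC and blastoderm differed with an exact permutation p of 0.10, as did PGC and GSC, and 0.10 is the smallest two-sided p that 3 against 3 arrays allow (0.20 after adjustment over all 20 quality tests). The poly-A spike-in controls stood at 7.43 ± 0.30 in PGC, 6.67 ± 0.51 in CEF, 4.83 ± 0.75 in GSC and 4.83 ± 0.80 in blastoderm. The number of cells per sample differed between the groups too, so these measures and the cell type cannot be told apart.

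**Figure D1:**
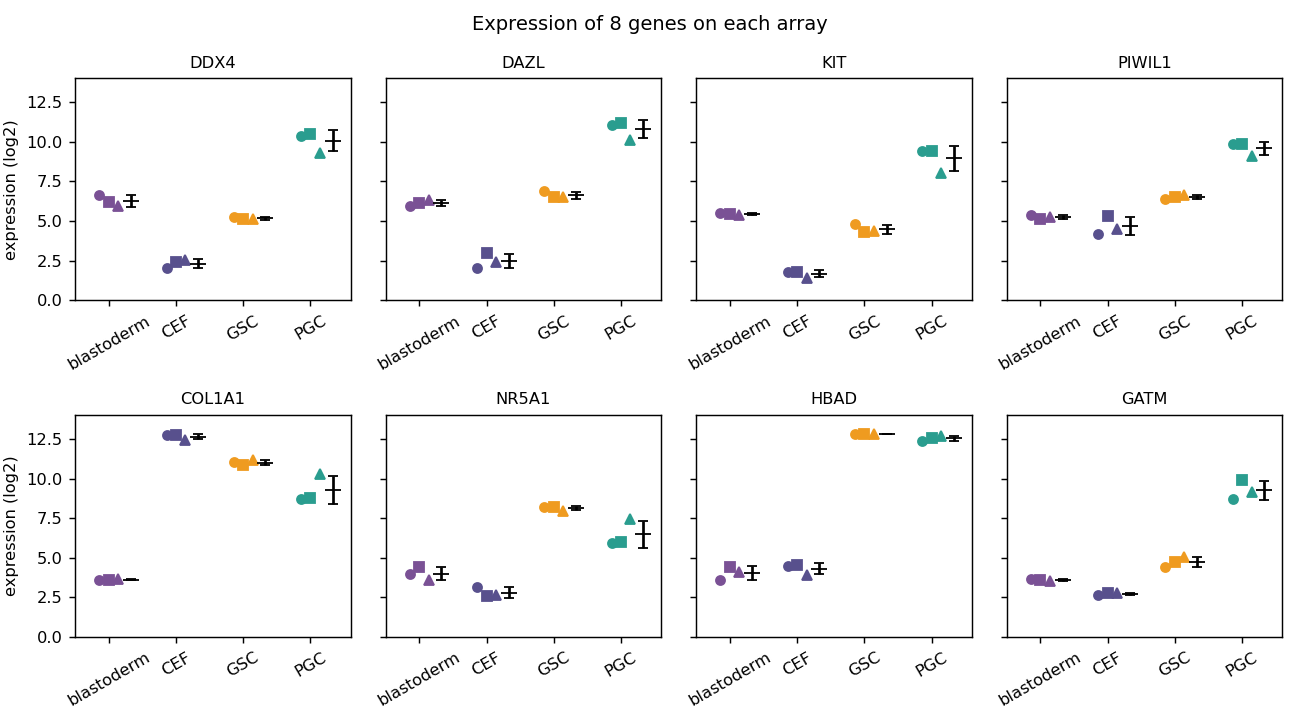
Expression (log2) of 8 genes on each of the 12 arrays, by group, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD of the 3 arrays. DDX4, DAZL, KIT and PIWIL1 were highest in PGC, COL1A1 in CEF, NR5A1 in GSC and GATM in PGC, and HBAD was above 12 in both gonadal groups.

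PGC and GSC came from the same organ at the same age, and comparing them asks which transcripts set germ cells apart from the somatic cells around them. DDX4, the vasa RNA helicase that marks germ cells, stood at 10.06 ± 0.66 in PGC and 5.19 ± 0.09 in GSC (mean ± SD, n = 3), a 29.2-fold difference (log2 4.87, SE 0.28, adjusted p = 1.29e-08). DAZL, a germ cell RNA-binding protein, was 18-fold higher (log2 4.17, SE 0.28). KIT, the receptor for stem cell factor, was 22.1-fold higher (log2 4.47, SE 0.30), and its ligand KITLG was 5.12-fold lower (log2 -2.36, SE 0.23). DMRTB1, a gene of the DM-domain family, showed the largest fold of the genes with an assigned symbol, 38.1-fold (log2 5.25, SE 0.23). The transcription factor genes SOX3 and OTX2 rose 32.9-fold (log2 5.04, SE 0.27) and 26.2-fold (log2 4.71, SE 0.24), and the Notch target HES5 25.5-fold (log2 4.67, SE 0.34). GATM, which makes the precursor of creatine, and DPYS, an enzyme of pyrimidine breakdown, were 22.8-fold and 22.1-fold higher. GATM is also on the kidney epithelium list taken up below, and its source in the PGC fraction is open. Lower in PGC were BMP5, a bone morphogenetic protein, by 6.38-fold, ESR1, the oestrogen receptor alpha, by 5.38-fold, and NFIA, a transcription factor, by 5.32-fold. The chemokine receptor CXCR4 was 6.38-fold higher (log2 2.67, SE 0.47), a call that ended with an offset of 64 added before the logarithm. KITLG, OTX2, BMP5, ESR1 and CXCR4 had a lower group within background.

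Across the 37693 probe sets tested, 4083 were higher in PGC than in GSC and 4166 were lower, of which 2146 and 1857 changed at least 2-fold. Higher calls were 49.5% of all calls, and 52.9% with every array centred on its median. At 16-fold or more there were 65 higher and 0 lower by limma (0 at an unadjusted p below 0.05), and the lowest log2 fold change among called probe sets was -2.99. The lower count was 2675 without PGC replicate 1, and with array weights the counts were 6370 higher and 7460 lower. GAPDH, an enzyme of glycolysis often used as a reference, was 11.81 ± 0.08 in PGC and 12.02 ± 0.10 in GSC and was not called (adjusted p = 0.145). It was called lower with array weights and without blastoderm replicate 1. ACTB, beta-actin, was 1.19-fold lower (log2 -0.25, SE 0.06), with another of its probe sets called in the opposite direction, and its call ended in a fit without the intensity trend. SOX2, a pluripotency factor, lay below background in both groups, and LIN28A, an RNA-binding protein of early cells, was 2.38-fold higher (log2 1.25, SE 0.20). NANOG, POU5F3, PRDM14 and WT1 have no probe set with that symbol.

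Germ cell gene sets rose. Of the germ plasm and PGC specification list, 14 of 21 rose, 2 fell and 5 did not pass, or 14 and 2 adjusted over the list alone. Adjusted p was 2.18e-08, at a median log2 fold change of 1.96, and adjusted p = 0.095 with an estimated correlation. DND1, a vertebrate germ plasm RNA-binding protein, was 18.4-fold higher (log2 4.20, SE 0.19), while MOV10, an RNA helicase, was 3.17-fold lower (log2 -1.66, SE 0.28). In the piRNA pathway, which silences transposons in germ cells, 15 of 18 rose, 0 fell and 3 did not pass, or 15 and 0 adjusted over the list alone. Adjusted p was 5.47e-11, at a median log2 fold change of 2.74, and adjusted p = 0.095 with an estimated correlation. Its members PNLDC1, a piRNA-trimming exonuclease, and FKBP6 were 18.1-fold and 15-fold higher. The meiosis list had 10 of 30 measured members higher and 1 lower (15 and 2 adjusted over the list alone). Adjusted p was 0.0118, at a median log2 fold change of 0.39, and adjusted p = 0.39 with an estimated correlation. HORMAD1 was 7.87-fold higher (log2 2.98, SE 0.24) and SYCP3, of the synaptonemal complex, 4.75-fold higher (log2 2.25, SE 0.27). For pluripotency, 16 of 27 rose, 2 fell and 9 did not pass, or 18 and 2 adjusted over the list alone. Adjusted p was 3.36e-08, at a median log2 fold change of 1.21, and adjusted p = 0.095 with an estimated correlation. ZIC2 was 18.4-fold higher (log2 4.20, SE 0.33) and CFC1, a co-receptor of nodal signalling, 2.15-fold lower (log2 -1.10, SE 0.22). HORMAD1 and SYCP3 had a lower group within background. In PGC replicate 3 the median level of the piRNA members was 5.85, against 7.55 and 7.36 in replicates 1 and 2, while that of the germ plasm members was 7.31, against 6.75 and 6.73.

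The kidney epithelium list was called higher beside the germ cell lists. The mesonephros and kidney epithelium list had 7 of 13 measured members higher and 2 lower (7 and 2 adjusted over the list alone). Adjusted p was 0.00295, at a median log2 fold change of 1.68, and adjusted p = 0.279 with an estimated correlation. SLC3A1, a cystine transporter, was 16-fold higher (SE 0.30 on the log2 scale), and LRP2, the megalin endocytic receptor, was 12.1-fold higher (log2 3.60, SE 0.33). UMOD, the uromodulin of the thick ascending limb, was 2.77-fold lower (log2 -1.47, SE 0.28), and PODXL, a sialomucin abundant in podocytes, was 3.72-fold lower (log2 -1.89, SE 0.38). The median level of the list was 6.82, 6.98 and 7.13 in the 3 PGC arrays and 3.82, 4.25 and 4.90 in the 3 GSC arrays.

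Somatic markers of the gonad fell but stayed measurable in PGC. The gonadal somatic list had 2 of 32 measured members higher and 16 lower (3 and 20 adjusted over the list alone). Adjusted p was 2.08e-04, at a median log2 fold change of -1.20, and adjusted p = 0.356 with an estimated correlation. NR5A1, steroidogenic factor 1, was 6.47 ± 0.85 in PGC and 8.13 ± 0.14 in GSC, 3.15-fold lower (log2 -1.65, SE 0.34), and LHX9, a gonad transcription factor, was 5.05-fold lower (log2 -2.34, SE 0.39). GATA4 was 5.83-fold lower (log2 -2.54, SE 0.49), and the change was -3.39 without PGC replicate 3. AMH, the anti-Müllerian hormone, was at 11.54 ± 0.71 in PGC and 12.20 ± 0.18 in GSC and was not called, but was called lower with array weights and without PGC replicate 3. The median level of the gonadal somatic members was 6.86 in PGC replicate 3, against 5.38 and 5.39 in the other PGC arrays.

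Matrix, cytoskeletal and vascular genes were lower in PGC. The extracellular matrix and fibroblast list had 2 of 42 measured members higher and 30 lower (2 and 36 adjusted over the list alone). Adjusted p was 5.47e-11, at a median log2 fold change of -1.17, and adjusted p = 0.219 with an estimated correlation. Type I collagen fell, COL1A1 by 3.33-fold (log2 -1.73, SE 0.28) and COL1A2 by 3.53-fold (log2 -1.82, SE 0.28), and so did MMP2, a gelatinase, which was 4.13-fold lower (log2 -2.05, SE 0.27). TIMP2, an inhibitor of such proteases, was 2.87-fold higher (log2 1.52, SE 0.26). Of the contractile cytoskeleton list, 1 of 20 rose, 9 fell and 10 did not pass, or 1 and 10 adjusted over the list alone. Adjusted p was 1.38e-04, at a median log2 fold change of -0.53, and adjusted p = 0.293 with an estimated correlation. CALD1, caldesmon, was 4.33-fold lower (log2 -2.11, SE 0.39). For endothelial markers, 0 of 22 rose, 12 fell and 10 did not pass, or 0 and 16 adjusted over the list alone. Adjusted p was 5.72e-06, at a median log2 fold change of -0.80, and adjusted p = 0.293 with an estimated correlation. KDR, the receptor of vascular endothelial growth factor, was 3.81-fold lower (log2 -1.93, SE 0.25). The erythroid list had 0 of 16 measured members higher and 8 lower (0 and 9 adjusted over the list alone). Adjusted p was 5.41e-04, at a median log2 fold change of -0.73, and adjusted p = 0.293 with an estimated correlation. HEMGN, an erythroid nuclear protein, was 2.78-fold lower (log2 -1.47, SE 0.33). The globin HBAD stood at 12.54 ± 0.17 in PGC and 12.80 ± 0.01 in GSC, near the highest values, where a difference may be hidden, and was called only in a model of these 2 groups alone. The matrix list had a median level of 7.38 in PGC replicate 3, against 6.29 in replicate 1. The erythroid list had 7.09 in replicate 3, against 5.73 and 6.14.

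Signalling, patterning, migration and respiration lists were called too. Of BMP, TGF-beta and activin signalling, 3 of 36 rose, 13 fell and 20 did not pass, or 3 and 15 adjusted over the list alone. Adjusted p was 0.00471, at a median log2 fold change of -0.42, and adjusted p = 0.343 with an estimated correlation. TGFBR3, betaglycan, was 5.21-fold lower (log2 -2.38, SE 0.21) and ID4 2.39-fold higher (log2 1.26, SE 0.22). Of the HOX genes, 3 of 27 rose, 10 fell and 14 did not pass, or 3 and 12 adjusted over the list alone. Adjusted p was 0.00811, at a median log2 fold change of -0.36, and adjusted p = 0.427 with an estimated correlation. HOXA9 was 3.4-fold lower (log2 -1.76, SE 0.28) and HOXD8 7.29-fold higher (log2 2.87, SE 0.23), and the call of the list ended with fry (adjusted p = 0.0646). The migration and homing list had 4 of 21 measured members higher and 11 lower (4 and 12 adjusted over the list alone). Adjusted p was 0.0377, at a median log2 fold change of -0.69, and adjusted p = 0.356 with an estimated correlation. Its mean log2 fold change of 0.05 differed in sign from its median and test. KIT, the adhesion molecule EPCAM (log2 4.15, SE 0.28) and the cadherin CDH1 (log2 3.39, SE 0.19) rose. That call ended with fry (adjusted p = 0.408) and without GSC replicate 2 (adjusted p = 0.0555). In oxidative phosphorylation, 15 of 60 rose, 1 fell and 44 did not pass, or 16 and 1 adjusted over the list alone. Adjusted p was 0.00234, at a median log2 fold change of 0.17, and adjusted p = 0.445 with an estimated correlation. The complex I subunit NDUFA5 was 2.11-fold higher (log2 1.08, SE 0.20). TGFBR3 and HOXD8 had a lower group within background.

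The other lists were not called in PGC versus GSC. Given as members higher and lower of those measured, then as both counts adjusted over the list alone, they were primitive endoderm and early axis (2 and 4 of 22, then 2 and 4, adjusted p = 0.665), leukocyte (0 and 1 of 19, then 0 and 1, adjusted p = 0.311) and skeletal muscle (7 and 1 of 20, then 7 and 2, adjusted p = 0.386). Likewise uncalled were neural (1 and 4 of 16, then 2 and 5, adjusted p = 0.248), cell cycle (3 and 3 of 37, then 3 and 3, adjusted p = 0.751) and glycolysis (6 and 2 of 19, then 8 and 2, adjusted p = 0.24). Uncalled too were tricarboxylic acid cycle (6 and 1 of 25, then 6 and 1, adjusted p = 0.126), DNA methylation and chromatin (6 and 8 of 26, then 7 and 8, adjusted p = 0.908) and immediate early and heat shock (5 and 9 of 24, then 7 and 9, adjusted p = 0.224). Single members stood out from them: DNMT3B, a de novo DNA methyltransferase, was 9.72-fold higher (log2 3.28, SE 0.22), and PCK1, the gluconeogenic enzyme, was 12.7-fold higher (log2 3.67, SE 0.24), with GSC within background. With fry the primitive endoderm, skeletal muscle and tricarboxylic acid cycle lists were called higher and the immediate early list lower (adjusted p = 0.015, 0.00183, 0.000976 and 0.0265). The median, mean and test of the skeletal muscle, cell cycle and chromatin lists differed in sign.

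**Figure D2:**
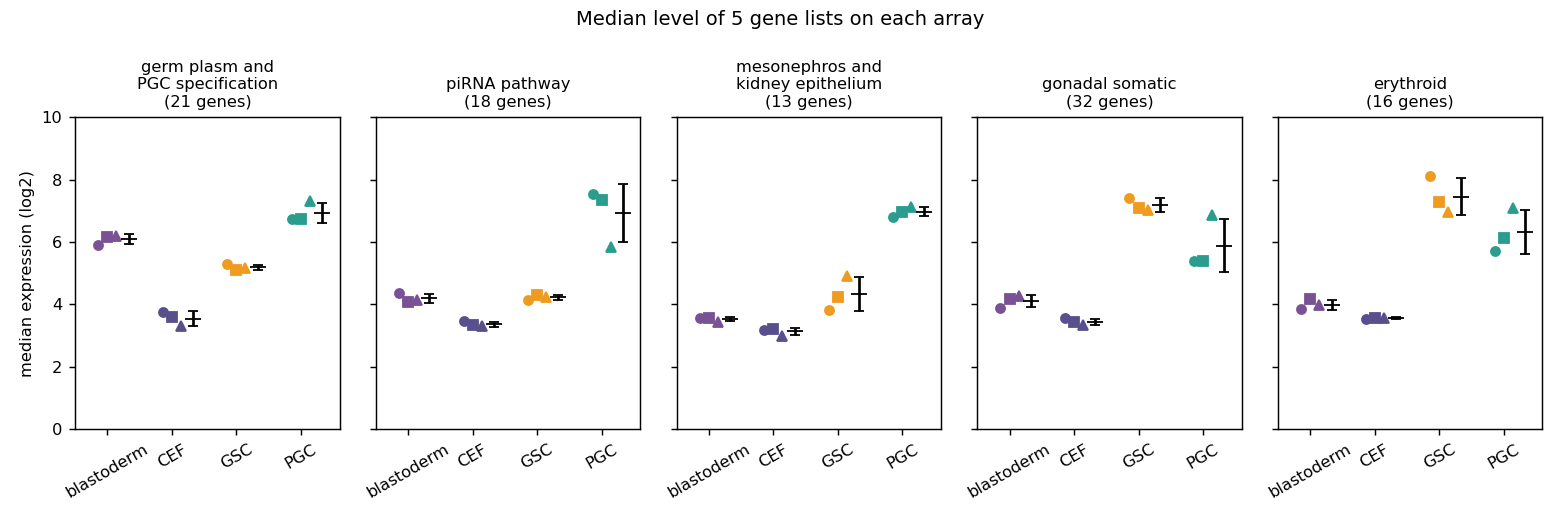
Median expression (log2) of the measured members of 5 gene lists on each array, by group, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD of the 3 arrays. In PGC replicate 3 the 5 medians, from left to right, were 7.31, 5.85, 7.13, 6.86 and 7.09, against 6.73 to 6.75, 7.36 to 7.55, 6.82 to 6.98, 5.38 to 5.39 and 5.73 to 6.14 in the other PGC arrays.

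This comparison sets germ cells of the gonad against dissociated cells of the freshly laid egg, whose mix of cell types was not tested. Germ cell transcripts were present in blastoderm and higher in PGC: DAZL stood at 6.15 ± 0.17 in blastoderm and 10.81 ± 0.58 in PGC (mean ± SD, n = 3), 25.1-fold higher (log2 4.65, SE 0.28). DDX4 was 13.8-fold higher (log2 3.79, SE 0.28) and KIT 11.4-fold higher (log2 3.51, SE 0.30), both above background in blastoderm. Among the genes lower in PGC were ASTL, a protease of the astacin family, by 176-fold, CCNA1, cyclin A1, by 101-fold, and WNT3A, a Wnt ligand, by 81.1-fold. MYC, the proliferation regulator, fell from 11.48 ± 0.33 to 5.69 ± 0.65, which is 55.3-fold (log2 -5.79, SE 0.29). The homeobox gene goosecoid was 41.2-fold lower and FOXA2, an endoderm factor, 34.9-fold lower. ASTL, CCNA1, WNT3A, goosecoid and FOXA2 had a lower group within background.

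The largest rises over blastoderm included secreted proteins, globins and a transporter. AvBD10, an avian beta-defensin, was 445-fold higher (log2 8.80, SE 0.25). The globins HBAD, HBBR, HBZ and HBA1, which carry oxygen in red blood cells, were 362-fold, 349-fold, 274-fold and 218-fold higher, and another probe set of HBAD was called in the opposite direction. SELENOP1, a plasma selenoprotein, was 229-fold higher and AMH 166-fold higher. SLC13A3, a dicarboxylate transporter, was 118-fold higher, and GSTA3, a glutathione transferase, 118-fold higher. In GSC, the levels of AMH, HBAD, HBBR and HBZ were 12.20, 12.80, 12.24 and 12.27. AvBD10, HBBR, HBZ, SELENOP1, SLC13A3 and GSTA3 had a lower group within background.

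In PGC versus blastoderm 6853 probe sets were higher and 7218 lower, of which 4251 and 3072 changed at least 2-fold. The chemokine receptor CXCR4 was 8.82-fold lower (log2 -3.14, SE 0.47) and LIN28A 2.23-fold lower (log2 -1.16, SE 0.20). SOX2 was within background in both groups (PGC 2.97, blastoderm 3.45), and its call (adjusted p = 0.0389) ended without any 1 of the blastoderm arrays and without PGC replicate 1 or 2. GAPDH was not called (adjusted p = 0.428), and ACTB was 1.18-fold lower (log2 -0.24, SE 0.06), with another probe set called in the opposite direction and the call lost without the intensity trend.

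The germ plasm and piRNA lists rose, and the early lineage lists fell. Of the germ plasm and PGC specification list, 13 of 21 rose, 5 fell and 3 did not pass, or 14 and 5 adjusted over the list alone. Adjusted p was 0.0111, at a median log2 fold change of 1.39, and adjusted p = 0.291 with an estimated correlation. TFAP2C and SOX17, transcription factors tied to germ cell specification in mammals, went the other way, 19.8-fold lower (log2 -4.31, SE 0.25) and 18.2-fold lower (log2 -4.19, SE 0.25). For the piRNA pathway, 13 of 18 rose, 1 fell and 4 did not pass, or 13 and 1 adjusted over the list alone. Adjusted p was 2.96e-05, at a median log2 fold change of 2.12, and adjusted p = 0.219 with an estimated correlation. PIWIL1, a Piwi protein, was 20.2-fold higher (log2 4.33, SE 0.26). The pluripotency list had 4 of 27 measured members higher and 14 lower (4 and 14 adjusted over the list alone). Adjusted p was 0.0114, at a median log2 fold change of -0.52, and adjusted p = 0.219 with an estimated correlation. EOMES, a T-box factor, was 9.75-fold lower (log2 -3.29, SE 0.25) and ZIC2 13.5-fold higher (log2 3.75, SE 0.33). The primitive endoderm and early axis list had 2 of 22 measured members higher and 16 lower (2 and 16 adjusted over the list alone). Adjusted p was 4.29e-06, at a median log2 fold change of -1.72, and adjusted p = 0.095 with an estimated correlation. FGF8, a growth factor of early axis formation, was 29.4-fold lower (log2 -4.88, SE 0.21), with PGC within background, and APOA1, an apolipoprotein, 12.9-fold higher (log2 3.69, SE 0.23).

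The cell cycle list was lower in PGC, the respiration lists higher. For the cell cycle list, 2 of 37 rose, 25 fell and 10 did not pass, or 2 and 28 adjusted over the list alone. Adjusted p was 5.91e-06, at a median log2 fold change of -0.78, and adjusted p = 0.239 with an estimated correlation. CCNE2, cyclin E2, was 6.39-fold lower (log2 -2.68, SE 0.28), AURKB, a mitotic kinase, 5.28-fold lower (log2 -2.40, SE 0.13) and TYMS, thymidylate synthase, 2.45-fold higher (log2 1.29, SE 0.18). Oxidative phosphorylation had 47 of 60 measured members higher and 2 lower (48 and 2 adjusted over the list alone). Adjusted p was 1.17e-09, at a median log2 fold change of 0.74, and adjusted p = 0.219 with an estimated correlation. The complex I subunits NDUFS4 and NDUFB2 rose 4.38-fold (log2 2.13, SE 0.28) and 3.45-fold (log2 1.79, SE 0.15). For the tricarboxylic acid cycle, 19 of 25 rose, 1 fell and 5 did not pass, or 20 and 1 adjusted over the list alone. Adjusted p was 6.38e-05, at a median log2 fold change of 0.62, and adjusted p = 0.095 with an estimated correlation. OGDHL, an oxoglutarate dehydrogenase subunit, was 10-fold higher (log2 3.32, SE 0.23) and IDH1, a cytosolic isocitrate dehydrogenase, 8.79-fold higher (log2 3.14, SE 0.22). The BMP, TGF-beta and activin list had 3 of 36 measured members higher and 21 lower (6 and 22 adjusted over the list alone). Adjusted p was 0.00592, at a median log2 fold change of -0.69, and adjusted p = 0.354 with an estimated correlation. BMP2 was 5.02-fold lower (log2 -2.33, SE 0.22), its target ID1 4.95-fold lower (log2 -2.31, SE 0.24) and the signal mediator SMAD3 7.51-fold higher (log2 2.91, SE 0.20).

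Somatic marker lists were also higher in PGC than in blastoderm. The extracellular matrix and fibroblast list had 29 of 42 measured members higher and 2 lower (29 and 3 adjusted over the list alone). Adjusted p was 1.52e-08, at a median log2 fold change of 2.05, and adjusted p = 0.279 with an estimated correlation. COL1A1 was 50.1-fold higher (log2 5.65, SE 0.28), COL1A2 62-fold higher (log2 5.95, SE 0.28) and COL3A1, type III collagen, 91.8-fold higher (log2 6.52, SE 0.18). Of the gonadal somatic list, 18 of 32 rose, 4 fell and 10 did not pass, or 19 and 4 adjusted over the list alone. Adjusted p was 3.99e-04, at a median log2 fold change of 1.25, and adjusted p = 0.372 with an estimated correlation. CYP19A1, the aromatase that makes oestrogen, was 69-fold higher (log2 6.11, SE 0.38), NR5A1 5.59-fold higher (log2 2.48, SE 0.34) and LHX9 16.1-fold higher (SE 0.39 on the log2 scale). GATA4 was 3.93-fold lower (log2 -1.98, SE 0.49), or -2.82 on the log2 scale without PGC replicate 3 and -1.39 without PGC replicate 1. The kidney list had 10 of 13 measured members higher and 0 lower (10 and 0 adjusted over the list alone). Adjusted p was 6.36e-05, at a median log2 fold change of 1.66, and adjusted p = 0.219 with an estimated correlation. CUBN, the cubilin receptor, was 51.3-fold higher (log2 5.68, SE 0.27). Of the erythroid members, 10 of 16 rose, 1 fell and 5 did not pass, or 11 and 1 adjusted over the list alone. Adjusted p was 1.92e-05, at a median log2 fold change of 2.17, and adjusted p = 0.219 with an estimated correlation. Of the endothelial members, 13 of 22 rose, 2 fell and 7 did not pass, or 14 and 2 adjusted over the list alone. Adjusted p was 0.0115, at a median log2 fold change of 1.27, and adjusted p = 0.516 with an estimated correlation. Its call ended with an offset of 64 (adjusted p = 0.0789). FLT4, a vascular receptor, was 5.33-fold higher (log2 2.41, SE 0.29). COL1A2, CYP19A1, LHX9 and CUBN had a lower group within background. In PGC the erythroid median was 6.14 or less in replicates 1 and 2 and 7.09 in replicate 3.

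Not called in PGC versus blastoderm, by the same reading, were meiosis (9 and 5 of 30, then 10 and 5, adjusted p = 0.665), contractile cytoskeleton (4 and 5 of 20, then 4 and 5, adjusted p = 0.893) and leukocyte (4 and 2 of 19, then 4 and 2, adjusted p = 0.855). Also without a call were skeletal muscle (3 and 4 of 20, then 3 and 4, adjusted p = 0.908), neural (4 and 3 of 16, then 4 and 3, adjusted p = 0.842) and glycolysis (7 and 7 of 19, then 8 and 7, adjusted p = 0.855). No call was made for DNA methylation and chromatin (4 and 11 of 26, then 4 and 13, adjusted p = 0.151), HOX (11 and 3 of 27, then 11 and 3, adjusted p = 0.151), immediate early and heat shock (7 and 7 of 24, then 7 and 9, adjusted p = 0.673) and migration and homing (10 and 5 of 21, then 11 and 5, adjusted p = 0.151). Among their members, CDH2, N-cadherin, was 19.2-fold higher (log2 4.26, SE 0.25) and EGR1, an immediate early transcription factor, 12.8-fold higher (log2 3.67, SE 0.26). With fry the neural, HOX and migration lists were called higher and the chromatin list lower (adjusted p = 0.00479, 0.0265, 0.000593 and 0.00138). The chromatin list was called with all probe sets (adjusted p = 0.0109), and the median, mean and test of the contractile cytoskeleton, skeletal muscle, neural and glycolysis lists differed in sign.

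CEF are somatic cells grown in culture, and the comparison shows how germ cells differ from cultured fibroblasts. DAZL rose from 2.49 ± 0.45 in CEF to 10.81 ± 0.58 in PGC (mean ± SD, n = 3), 319-fold higher (log2 8.32, SE 0.28). DDX4 was 213-fold higher (log2 7.73, SE 0.28) and KIT 154-fold higher (log2 7.27, SE 0.30). EPCAM and CLDN1, which join epithelial cells, were 260-fold and 234-fold higher, and DMRT1, a sex-determination factor of the gonad, 278-fold higher. AvBD10 was 549-fold, AMH 305-fold and HBAD 302-fold higher. RGN, a calcium-binding protein called regucalcin, was 215-fold higher, with another of its probe sets called in the opposite direction. Among the genes lower in PGC than in CEF, LGALS1A, a galectin, was 419-fold lower (log2 -8.71, SE 0.21), INHBA, a subunit of activin, 282-fold lower (log2 -8.14, SE 0.19) and TAGLN, transgelin, 216-fold lower (log2 -7.75, SE 0.22). The cell cycle inhibitor CDKN2A was 101-fold, the tendon factor MKX 133-fold and the fibroblast surface protein THY1 76.7-fold lower. DAZL, DDX4, KIT, EPCAM, DMRT1, AvBD10, AMH, LGALS1A, INHBA, CDKN2A, MKX and THY1 had a lower group within background.

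In this comparison 7376 probe sets were higher in PGC and 7168 lower, of which 4221 and 3024 changed at least 2-fold. Centring every array on its median turned this balance, to 6842 higher and 8727 lower. CXCR4 was 3.11-fold higher (log2 1.64, SE 0.47) at an adjusted p of 0.011. That call ended without CEF replicate 1 or 2 and with an offset of 64, and the change was 2.29 without CEF replicate 3. LIN28A was 1.76-fold higher (log2 0.82, SE 0.20), and SOX2 was 1.53-fold lower (log2 -0.61, SE 0.18) with both groups within background. GAPDH was 1.34-fold lower (log2 -0.42, SE 0.10) and ACTB 1.77-fold lower (log2 -0.82, SE 0.06). GATA4 was 3.25-fold higher (log2 1.70, SE 0.49), with CEF within background, a call that ended with an offset of 16 or 64, and its change was 0.86 without PGC replicate 3 and 2.29 without PGC replicate 1.

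Germ cell, meiotic and pluripotency lists were higher in PGC. Of the germ plasm and PGC specification list, 16 of 21 rose, 1 fell and 4 did not pass, or 17 and 1 adjusted over the list alone. Adjusted p was 2.68e-07, at a median log2 fold change of 2.49, and adjusted p = 0.095 with an estimated correlation. KLF2, a transcription factor, was 3.94-fold lower (log2 -1.98, SE 0.27). For the piRNA pathway, 14 of 18 rose, 1 fell and 3 did not pass, or 14 and 1 adjusted over the list alone. Adjusted p was 3.60e-06, at a median log2 fold change of 2.84, and adjusted p = 0.219 with an estimated correlation. PIWIL1 was 30.4-fold higher (log2 4.93, SE 0.26). The meiosis list had 13 of 30 measured members higher and 0 lower (15 and 2 adjusted over the list alone). Adjusted p was 0.0102, at a median log2 fold change of 0.43, and adjusted p = 0.375 with an estimated correlation. HORMAD1 was 11.2-fold higher (log2 3.49, SE 0.24). The pluripotency list had 18 of 27 measured members higher and 3 lower (18 and 3 adjusted over the list alone). Adjusted p was 1.92e-05, at a median log2 fold change of 1.31, and adjusted p = 0.095 with an estimated correlation. DNMT3B was 181-fold higher (log2 7.50, SE 0.22), SOX3 76.8-fold higher (log2 6.26, SE 0.27) and OTX2 43.9-fold higher (log2 5.46, SE 0.24). HORMAD1 and OTX2 had a lower group within background.

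Matrix and contractile genes had the lowest list medians in this comparison. The extracellular matrix and fibroblast list had 1 of 42 measured members higher and 37 lower (1 and 37 adjusted over the list alone). Adjusted p was 3.88e-17, at a median log2 fold change of -3.04, and adjusted p = 0.167 with an estimated correlation. TNC, tenascin C, was 64.8-fold lower (log2 -6.02, SE 0.23), with PGC within background, COL1A1 10.3-fold lower (log2 -3.37, SE 0.28) and COL1A2 9.71-fold lower (log2 -3.28, SE 0.28). Of the contractile cytoskeleton list, 0 of 20 rose, 19 fell and 1 did not pass, or 0 and 19 adjusted over the list alone. Adjusted p was 1.40e-13, at a median log2 fold change of -2.61, and adjusted p = 0.095 with an estimated correlation. CALD1 was 45.7-fold lower (log2 -5.51, SE 0.39) and CSRP1, a LIM-domain protein, 38.2-fold lower (log2 -5.26, SE 0.23). The leukocyte list had 0 of 19 measured members higher and 11 lower (0 and 13 adjusted over the list alone). Adjusted p was 8.19e-05, at a median log2 fold change of -1.42, and adjusted p = 0.293 with an estimated correlation. CTSS, cathepsin S, was 10.5-fold lower (log2 -3.40, SE 0.30). For BMP, TGF-beta and activin signalling, 5 of 36 rose, 14 fell and 17 did not pass, or 6 and 15 adjusted over the list alone. Adjusted p was 0.0412, at a median log2 fold change of -0.31, and adjusted p = 0.441 with an estimated correlation. TGFB1, a transforming growth factor beta, was 16.6-fold lower (log2 -4.05, SE 0.25). The call of the BMP list ended without CEF replicate 3 (adjusted p = 0.0594), PGC replicate 1 (0.111) or PGC replicate 2 (0.0533).

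Somatic marker lists of the gonad, kidney and erythroid cells were higher in PGC than in CEF. Of the gonadal somatic list, 22 of 32 rose, 3 fell and 7 did not pass, or 24 and 3 adjusted over the list alone. Adjusted p was 1.40e-05, at a median log2 fold change of 1.60, and adjusted p = 0.311 with an estimated correlation. CYP19A1 was 68.9-fold higher (log2 6.11, SE 0.38), NR5A1 12.7-fold higher (log2 3.67, SE 0.34) and LHX9 11-fold higher (log2 3.45, SE 0.39). The kidney list had 10 of 13 measured members higher and 1 lower (11 and 1 adjusted over the list alone). Adjusted p was 8.01e-05, at a median log2 fold change of 2.23, and adjusted p = 0.219 with an estimated correlation. GATM was 91.3-fold higher (log2 6.51, SE 0.26) and SLC12A1, the salt transporter of the thick ascending limb, 42.8-fold higher (log2 5.42, SE 0.37). Of the erythroid list, 13 of 16 rose, 0 fell and 3 did not pass, or 13 and 0 adjusted over the list alone. Adjusted p was 3.36e-08, at a median log2 fold change of 3.18, and adjusted p = 0.167 with an estimated correlation. HBBR was 296-fold higher (log2 8.21, SE 0.21) and HBZ 243-fold higher (log2 7.92, SE 0.34). CYP19A1, NR5A1, LHX9, GATM, SLC12A1, HBBR and HBZ had a lower group within background.

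The cell cycle and respiration lists were higher in PGC, the glycolysis list lower. For the cell cycle list, 25 of 37 rose, 3 fell and 9 did not pass, or 26 and 3 adjusted over the list alone. Adjusted p was 1.27e-04, at a median log2 fold change of 0.75, and adjusted p = 0.293 with an estimated correlation. TYMS was 7.67-fold higher (log2 2.94, SE 0.18) and CDT1, a replication licensing factor, 3.96-fold higher (log2 1.99, SE 0.20). Oxidative phosphorylation had 42 of 60 measured members higher and 0 lower (43 and 0 adjusted over the list alone). Adjusted p was 2.06e-07, at a median log2 fold change of 0.58, and adjusted p = 0.279 with an estimated correlation. NDUFS4 was 4.07-fold higher (log2 2.02, SE 0.28) and NDUFA5 3.33-fold higher (log2 1.74, SE 0.20). For the tricarboxylic acid cycle, 13 of 25 rose, 2 fell and 10 did not pass, or 13 and 2 adjusted over the list alone. Adjusted p was 0.0115, at a median log2 fold change of 0.48, and adjusted p = 0.219 with an estimated correlation. MDH1, a malate dehydrogenase, was 2.56-fold higher (log2 1.36, SE 0.11). Of the glycolysis list, 2 of 19 rose, 11 fell and 6 did not pass, or 3 and 14 adjusted over the list alone. Adjusted p was 0.00435, at a median log2 fold change of -0.42, and adjusted p = 0.293 with an estimated correlation. The glucose transporter SLC2A1 was 6.26-fold lower (log2 -2.65, SE 0.21), ENO2, an enolase, 4.68-fold lower (log2 -2.23, SE 0.24) and LDHB, a lactate dehydrogenase, 1.59-fold higher (log2 0.67, SE 0.08).

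The skeletal muscle and HOX lists passed narrowly. The skeletal muscle list had 4 of 20 measured members higher and 9 lower (4 and 9 adjusted over the list alone). Adjusted p was 0.0452, at a median log2 fold change of -0.33, and adjusted p = 0.219 with an estimated correlation. ACTA1, skeletal actin, was 14.4-fold lower (log2 -3.85, SE 0.22) and TNNC1, a troponin, 4.61-fold higher (log2 2.20, SE 0.30). The sample labels name the muscular area as the source of CEF, which was not tested as a cause. The call of the muscle list also ended in 8 other settings, among them those without PGC replicate 3 (adjusted p = 0.0669), PGC replicate 2 (0.0625), CEF replicate 1 (0.0512) and blastoderm replicate 1 (0.0524). Of the HOX genes, 2 of 27 rose, 10 fell and 15 did not pass, or 2 and 10 adjusted over the list alone. Adjusted p was 0.0417, at a median log2 fold change of -0.36, and adjusted p = 0.528 with an estimated correlation. HOXD11 was 6.49-fold lower (log2 -2.70, SE 0.31), PGC being within background. The call of the HOX list ended without PGC replicate 1 (adjusted p = 0.153), PGC replicate 2 (0.104) or CEF replicate 1 (0.0646), with either offset (0.0621 and 0.0829) and with fry (0.0595). Not called, by the same reading as above, were primitive endoderm and early axis (6 and 4 of 22, then 6 and 5, adjusted p = 0.674), endothelial (8 and 3 of 22, then 8 and 3, adjusted p = 0.468) and neural (5 and 3 of 16, then 6 and 3, adjusted p = 0.429). The test did not pass for DNA methylation and chromatin (7 and 5 of 26, then 7 and 5, adjusted p = 0.395), immediate early and heat shock (9 and 7 of 24, then 9 and 7, adjusted p = 0.785) and migration and homing (6 and 9 of 21, then 6 and 10, adjusted p = 0.488). With fry the primitive endoderm, neural, chromatin and migration lists were called higher (adjusted p = 0.000659, 8.27e-06, 5.89e-05 and 0.0135). The median, mean and test of the endothelial and the migration and homing lists differed in sign, and the integrins ITGB3 and ITGAV of the latter were 9.32-fold and 8.86-fold lower.

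**Figure D3:**
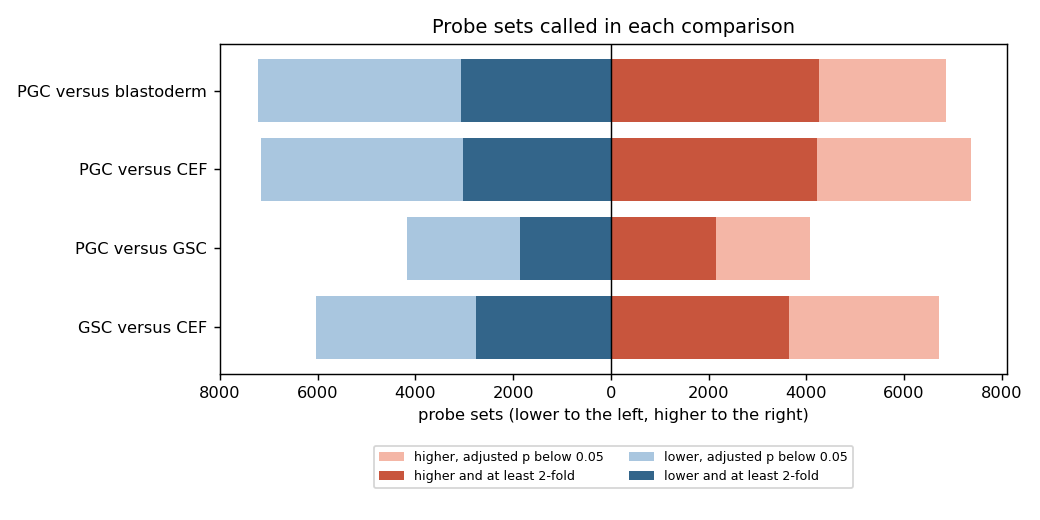
Number of probe sets called higher (right) and lower (left) in each of the 4 comparisons at an adjusted p below 0.05, with those that changed at least 2-fold in darker colour. PGC versus GSC had the fewest, 4083 higher and 4166 lower, and PGC versus CEF 7376 and 7168.

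GSC versus CEF sets somatic cells of the gonad against cultured fibroblasts. Gonadal genes were higher in GSC: AMH was at 12.20 ± 0.18 against 3.29 ± 0.14 in CEF (mean ± SD, n = 3), 482-fold higher (log2 8.91, SE 0.28). DMRT1 was 285-fold higher (log2 8.15, SE 0.18) and CYP19A1 211-fold higher (log2 7.72, SE 0.38). DSP, a desmosome protein, was 152-fold higher and COL4A5, a basement membrane collagen, 151-fold higher. The globins HBZ, HBBR, HBAD, HBA1 and HBE were 477-fold, 413-fold, 360-fold, 237-fold and 227-fold higher. Lower in GSC were INHBA, 243-fold (log2 -7.93, SE 0.19), LGALS1A, 229-fold (log2 -7.84, SE 0.21), and TAGLN, 167-fold (log2 -7.38, SE 0.22). The cell cycle inhibitors CDKN2A and CDKN2B were 87.5-fold and 87-fold lower, the chemokine CCL4 82.6-fold, FAP, a fibroblast surface protease, 84.5-fold and MKX 82.2-fold. AMH, DMRT1, CYP19A1, DSP, COL4A5, HBZ, HBBR, INHBA, CDKN2A, CDKN2B, CCL4, FAP and MKX had a lower group within background.

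Some germ cell transcripts were higher in GSC than in CEF, while the piRNA and meiosis lists were not called. DAZL was 17.7-fold higher (log2 4.15, SE 0.28), DDX4 7.28-fold higher (log2 2.86, SE 0.28) and KIT 6.97-fold higher (log2 2.80, SE 0.30). The calls of DDX4 and KIT ended with an offset of 64. For the germ plasm and PGC specification list, 7 of 21 rose, 1 fell and 13 did not pass, or 8 and 1 adjusted over the list alone. Adjusted p was 0.0417, at a median log2 fold change of 0.23, and adjusted p = 0.356 with an estimated correlation. ELAVL2, an RNA-binding protein, was 20.1-fold higher (log2 4.33, SE 0.26). That list's call ended with an offset of 16 (adjusted p = 0.11) or 64 (0.235) and without CEF replicate 1 (0.0536). DAZL, DDX4, KIT and ELAVL2 had a lower group within background.

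Over all probe sets 6715 were higher in GSC than in CEF and 6029 lower, of which 3643 and 2752 changed at least 2-fold. The share of calls that were higher was 52.7% and became 42.1% when every array was centred on its median. SOX2 was 1.5-fold lower (log2 -0.59, SE 0.18) with both groups within background, a call that ended without GSC replicate 2. LIN28A was not called (adjusted p = 0.103) but was called lower with quantile normalization, with median centring and without the intensity trend. CXCR4 was not called (adjusted p = 0.105), with GSC within background, but was called lower with array weights and without CEF replicate 1. GAPDH was not called (adjusted p = 0.116) but was called lower with median centring, without blastoderm replicate 1 and with only the arrays of GSC and CEF in the model. ACTB was 1.49-fold lower (log2 -0.58, SE 0.06).

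Lists of the gonad and its other cell types were higher in GSC. Of the gonadal somatic list, 25 of 32 rose, 2 fell and 5 did not pass, or 26 and 2 adjusted over the list alone. Adjusted p was 1.59e-09, at a median log2 fold change of 3.02, and adjusted p = 0.219 with an estimated correlation. NR5A1 was 40-fold higher (log2 5.32, SE 0.34), LHX9 55.3-fold higher (log2 5.79, SE 0.39) and GATA4 18.9-fold higher (log2 4.24, SE 0.49). The erythroid list had 13 of 16 measured members higher and 0 lower (16 and 0 adjusted over the list alone). Adjusted p was 1.66e-12, at a median log2 fold change of 4.13, and adjusted p = 0.095 with an estimated correlation. For endothelial markers, 12 of 22 rose, 1 fell and 9 did not pass, or 13 and 1 adjusted over the list alone. Adjusted p was 1.74e-04, at a median log2 fold change of 0.65, and adjusted p = 0.356 with an estimated correlation. KDR was 19-fold higher (log2 4.25, SE 0.25) and SOX7, a vascular transcription factor, 25.8-fold higher (log2 4.69, SE 0.24). The kidney list had 6 of 13 measured members higher and 1 lower (7 and 1 adjusted over the list alone). Adjusted p was 0.0232, at a median log2 fold change of 0.86, and adjusted p = 0.356 with an estimated correlation. PODXL was 20.3-fold higher (log2 4.34, SE 0.38) and UMOD 11.7-fold higher (log2 3.54, SE 0.28). The kidney call ended without GSC replicate 3 (adjusted p = 0.0597), with means over probe sets (0.0891), with all probe sets (0.282) and with an offset of 16 (0.0722) or 64 (0.165). Of the cell cycle list, 27 of 37 rose, 2 fell and 8 did not pass, or 27 and 3 adjusted over the list alone. Adjusted p was 1.49e-06, at a median log2 fold change of 0.70, and adjusted p = 0.219 with an estimated correlation. MCM2, a replication helicase subunit, was 3.77-fold higher (log2 1.91, SE 0.17). Oxidative phosphorylation had 31 of 60 measured members higher and 2 lower (32 and 2 adjusted over the list alone). Adjusted p was 1.27e-04, at a median log2 fold change of 0.34, and adjusted p = 0.356 with an estimated correlation. NDUFA6 was 2.01-fold higher (log2 1.01, SE 0.16). NR5A1, LHX9, GATA4, KDR, SOX7 and UMOD had a lower group within background.

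Matrix, contractile, leukocyte, muscle and glycolysis lists were lower in GSC. The extracellular matrix and fibroblast list had 3 of 42 measured members higher and 30 lower (3 and 32 adjusted over the list alone). Adjusted p was 2.95e-10, at a median log2 fold change of -1.79, and adjusted p = 0.237 with an estimated correlation. THY1 was 62.2-fold lower (log2 -5.96, SE 0.21), TNC 45.9-fold lower (log2 -5.52, SE 0.23), COL1A1 3.1-fold lower (log2 -1.63, SE 0.28) and COL1A2 2.75-fold lower (log2 -1.46, SE 0.28). Of the contractile cytoskeleton list, 0 of 20 rose, 17 fell and 3 did not pass, or 0 and 18 adjusted over the list alone. Adjusted p was 1.65e-11, at a median log2 fold change of -1.98, and adjusted p = 0.112 with an estimated correlation. CAV1, caveolin, was 21.7-fold lower (log2 -4.44, SE 0.18). The leukocyte list had 1 of 19 measured members higher and 11 lower (1 and 13 adjusted over the list alone). Adjusted p was 1.78e-04, at a median log2 fold change of -1.54, and adjusted p = 0.317 with an estimated correlation. PTPRC, the leukocyte antigen CD45, was 8.79-fold lower (log2 -3.14, SE 0.24). For skeletal muscle, 0 of 20 rose, 7 fell and 13 did not pass, or 0 and 7 adjusted over the list alone. Adjusted p was 0.00777, at a median log2 fold change of -0.22, and adjusted p = 0.112 with an estimated correlation. ACTA1 was 50.2-fold lower (log2 -5.65, SE 0.22), where the muscular source of CEF named above applies too. Of the glycolysis list, 2 of 19 rose, 11 fell and 6 did not pass, or 2 and 11 adjusted over the list alone. Adjusted p was 2.08e-04, at a median log2 fold change of -0.60, and adjusted p = 0.219 with an estimated correlation. LDHA, a lactate dehydrogenase, was 5.56-fold lower (log2 -2.47, SE 0.24). THY1, TNC and CAV1 had a lower group within background.

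Not called in GSC versus CEF, by the same reading, were piRNA pathway (3 and 1 of 18, then 3 and 1, adjusted p = 0.335), meiosis (7 and 1 of 30, then 7 and 1, adjusted p = 0.414) and pluripotency (8 and 5 of 27, then 8 and 5, adjusted p = 0.386). Not passed by the test were primitive endoderm and early axis (4 and 5 of 22, then 4 and 5, adjusted p = 0.791), neural (6 and 1 of 16, then 6 and 2, adjusted p = 0.0846) and tricarboxylic acid cycle (9 and 3 of 25, then 10 and 4, adjusted p = 0.0602). Without a call stood DNA methylation and chromatin (8 and 4 of 26, then 8 and 4, adjusted p = 0.24), HOX (7 and 10 of 27, then 7 and 10, adjusted p = 0.855) and immediate early and heat shock (8 and 6 of 24, then 9 and 6, adjusted p = 0.48). Beside these, no call was reached for migration and homing (8 and 6 of 21, then 8 and 6, adjusted p = 0.502) and BMP, TGF-beta and activin signalling (12 and 12 of 36, then 14 and 12, adjusted p = 0.845). Without GSC replicate 1 the neural list was called (adjusted p = 0.0471), and the tricarboxylic acid cycle list was called without GSC replicate 3 (0.0464) or blastoderm replicate 1 (0.0446) and with quantile normalization (0.0318). With all probe sets the neural, tricarboxylic acid cycle and chromatin lists were called (adjusted p = 0.013, 0.0112 and 0.0259). With fry the pluripotency, primitive endoderm, neural and tricarboxylic acid cycle lists were called higher (adjusted p = 0.000411, 0.0464, 1.00e-05 and 0.000107). So were the chromatin and migration lists (0.000197 and 0.00451), and the BMP list was called lower (0.00864). CFC1, of the pluripotency list, was 92.8-fold higher (log2 6.54, SE 0.22), CEF being within background. The median, mean and test of the pluripotency, HOX and BMP lists differed in sign.

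**Figure D4:**
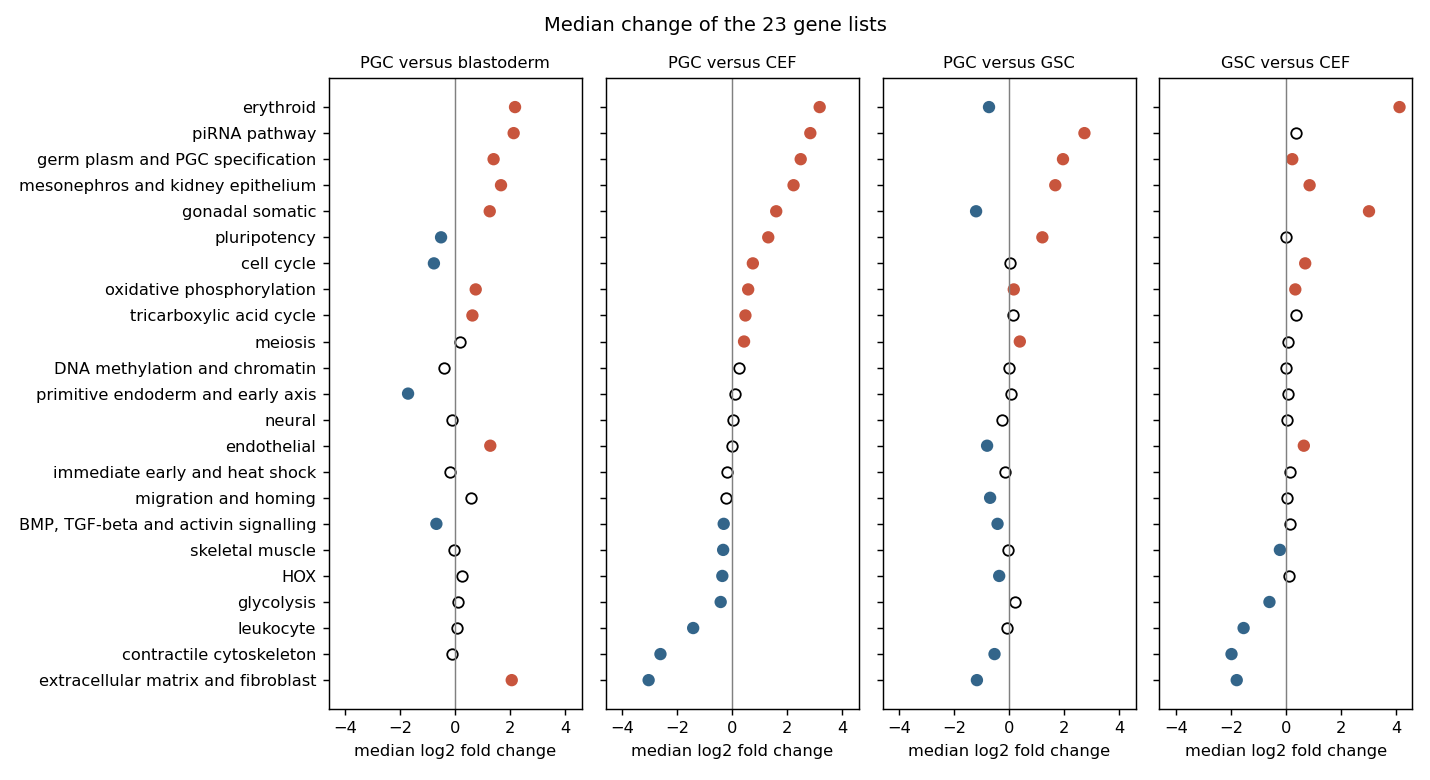
Median log2 fold change of the 23 gene lists in the 4 comparisons, with filled points for lists called at an adjusted p below 0.05 (red higher, blue lower in the first-named group), none of which held with an estimated correlation, and open points for the others. The germ plasm and PGC specification list had medians of 1.39, 2.49, 1.96 and 0.23, and the extracellular matrix and fibroblast list of 2.05, -3.04, -1.17 and -1.79.

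Probe sets called in the same direction in all 3 PGC comparisons describe what set PGC apart from each other group. There were 1802 higher (945 genes) and 420 lower (198 genes). Simulated groups without changes gave 0 of either in 20 runs, which the adjustment nearly assured, so it says nothing on whether these sets are particular to PGC. Independent comparisons with these numbers of calls would give 145.3 and 151.7. The 3 comparisons share the PGC arrays, so part of the excess may come from these. The lower count was 208 without PGC replicate 1, 254 without GSC replicate 2, 702 without PGC replicate 3 and 984 with array weights. By the smallest of the 3 folds, the highest genes were DMRTB1 (38.1-fold), HES5 (25.5-fold), PDZK1P1 (24.8-fold), CMBL (23.7-fold), GATM (22.8-fold) and DPYS (22.1-fold). HGD, an enzyme of tyrosine breakdown, SLC13A3, UGT1A1, a glucuronosyltransferase, and TUBA3E, an alpha-tubulin, followed with 21.2-fold, 20.7-fold, 20.2-fold and 19.3-fold. PDZK1P1, CMBL and HGD were within background in all 3 other groups, so that their folds depend on the floor. Of the lists, 11 of 21 germ plasm, 12 of 18 piRNA, 7 of 30 meiosis and 7 of 13 kidney members were in this set. GATM is 1 of these kidney members, and whether germ cells or other cells of the PGC fraction express them is open. The same is open for PDZK1P1, CMBL, DPYS, HGD, SLC13A3 and UGT1A1, whose source was not tested. The lowest genes were MYC, HAS2, which makes hyaluronan, and the transcription factor GATA6, at 3.6-fold, 3.51-fold and 3.38-fold lower, with PGC within background for HAS2.

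PGC and blastoderm were also set together against both somatic groups. There were 910 probe sets higher (522 genes) and 880 lower (448 genes) in both than in CEF and in GSC. Simulation without changes gave 0 of either in 20 runs, again nearly assured by the adjustment, and independent comparisons would give 30.7 and 26.6. The comparisons share the arrays of all 4 groups, so part of this excess too may come from shared arrays. With array weights the counts were 1511 and 1463, and the lower count was 556 without PGC replicate 1. SOX3 led with a smallest fold of 32.9, followed by OTX2 (26.2), EPCAM (17.8), the phosphate transporter SLC34A2 (17.4) and CLDN1 (14.4). CEF and GSC were within background for OTX2 and SLC34A2. SALL4, a zinc finger factor of stem and germ cells, had a smallest fold of 12.8, with 7.73 ± 0.41 in PGC and 10.16 ± 0.15 in blastoderm. ESRP2, an epithelial splicing regulator, had 13.9. Lower in both were AKR1B10, an aldo-keto reductase (5.32-fold), the integrin ITGA8 (4.94-fold), CALD1 (4.33-fold), MMP2 (4.13-fold) and the cadherin CDH11 (4.06-fold). DCN, decorin, and POSTN, periostin, were at 8.35 ± 1.09 and 7.72 ± 0.66 in PGC, at 2.39 ± 0.64 and 1.63 ± 0.21 in blastoderm and at 10.27 ± 0.36 and 9.62 ± 0.49 in GSC.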

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

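No test was run on the signal given here, which was seen only in the data. One of the 746 probe sets for viral and reporter sequences, which the comparisons do not use, stood far above the background level of 3.61. Its mean was 10.51 ± 0.26 in CEF, 9.70 ± 0.25 in GSC, 8.04 ± 0.76 in PGC and 5.71 ± 1.05 in blastoderm (log2, SD, n = 3). A second of them had lower means of 5.89 ± 0.28 in GSC, 5.09 ± 1.10 in CEF, 4.25 ± 0.81 in PGC and 2.96 ± 0.42 in blastoderm. No explanation was tested.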

How the results depend on the processing

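No test in this part was chosen after its result was seen. Of the settings for genes named in the text, no direction reversed; leaving out 1 array ended 147 calls and added 41, with 7012 the same, and the other settings ended 142 and added 67, with 6387 the same. For lists, leaving out 1 array ended 13 calls and added 3, and the other settings ended 72, 56 of them by an estimated correlation, added 23, 18 of them by fry, and reversed 1. An offset of 64 moved the fold of 65 of 105 called named genes by over 1.5 times in PGC versus GSC and ended 9 calls, against 90 of 123 and 6 in PGC versus blastoderm, 101 of 132 and 5 in PGC versus CEF and 80 of 114 and 19 in GSC versus CEF. Signal over background limits such folds, and 40.8% of probe sets had no group above background. The cause was not tested for any change below, except where a stricter minimum or fewer arrays by construction gives fewer calls. With a 2-fold minimum the counts of higher and lower probe sets were 4251 and 3072 in PGC versus blastoderm, 4221 and 3024 in PGC versus CEF, 2146 and 1857 in PGC versus GSC and 3643 and 2752 in GSC versus CEF. By the same minimum 951 and 79 were higher and lower in PGC than in each other group, and 380 and 377 in PGC and blastoderm than in CEF and GSC. With array weights PGC versus GSC gave 6370 and 7460, the set lower in PGC 984, and the sets of PGC and blastoderm 1511 and 1463. An offset of 64 gave 245 lower in PGC. The other settings, centring, quantile normalization, no trend, a robust prior, the low-value filter, an offset of 16 and the block, kept these counts within 1.5 times, as did 2 groups alone for the 4 comparisons, which was not run for the sets across groups.

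Leaving out 1 array moved 3 counts beyond 1.5 times: lower in PGC versus GSC from 2675 (without PGC replicate 1) to 5117 (without PGC replicate 3), lower in PGC than in each other group from 208 to 702 by the same arrays (254 without GSC replicate 2), and lower in PGC and blastoderm from 556 to 1196. With an estimated correlation 0 lists were called in PGC versus blastoderm, 0 in PGC versus CEF, 0 in PGC versus GSC and 0 in GSC versus CEF, so all 56 calls ended. With fry 19 lists were called in GSC versus CEF, and the migration and homing list in PGC versus CEF reversed (adjusted p = 0.0135). The RNA integrity difference of PGC and GSC was 0.44 by actin alone and 0.02 by GAPDH alone. With the low-value filter the median correlation of PGC with blastoderm was 0.794, with CEF 0.761 and with GSC 0.883, and that of GSC with CEF 0.799.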

Other observations

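The tests on PGC replicate 3 and on the kidney genes were chosen only after the result was seen, while the tests on the floor, on the GSC marker genes and on other splits of the arrays were set before their own values were seen, but after the patterns they address. Further genes that the rule for named genes picked add to the account above. In PGC versus GSC, OGN, osteoglycin of the extracellular matrix, was 6.25-fold lower (log2 -2.64, SE 0.29), and PDGFRA, a growth factor receptor of mesenchyme, 5.93-fold lower (log2 -2.57, SE 0.39). In PGC versus blastoderm MT3, a metallothionein, was 35.2-fold lower and RBP4A, a retinol-binding protein, 35.2-fold lower. In PGC versus CEF THBS2, a thrombospondin, was 84.8-fold and ACTG2, a smooth muscle actin, 85-fold lower. OGN, PDGFRA, RBP4A and THBS2 had a lower group within background.

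Of 13050 genes, 945 were higher in PGC than in each other group. These held 12 of 60 measured oxidative phosphorylation members, NDUFA5 and NDUFA8 among them, and 0 of 19 of glycolysis. They held 2 of 27 HOX genes, HOXD4 and HOXD8, and 4 of 25 of the tricarboxylic acid cycle list, ACO1, MDH1, PCK1 and PCK2. No share was tested. The set lower in PGC held 2 glycolysis members. The call of NDUFA8 in PGC versus blastoderm ended without blastoderm replicate 1 (adjusted p = 0.0521) or 3 (0.0587) and without PGC replicate 1 (0.0673) or 2 (0.0505). Of the pluripotency list, 14 of 27 were higher in both PGC and blastoderm than in CEF and GSC, among them SALL4, SOX3, OTX2 and DNMT3B. FGF13, a fibroblast growth factor homologue, had a smallest fold of 13.9 in that set, and COL6A2, a type VI collagen chain, one of 3.79 among the genes lower in both, with CEF and GSC within background for FGF13.

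PGC replicate 3 lay nearest the GSC arrays, and its RNA may hold a larger part from gonadal somatic cells. If PGC replicate 3 is a mixture of PGC replicates 1 and 2 with GSC, 212 genes high in GSC give a GSC share of 37.8% (quartiles 25.8 and 51.1). At that share 23 germ plasm and piRNA members would change by -0.61 and changed by -0.96 (medians, median difference -0.38, SD 0.62), but the 7 called kidney members would change by -0.62 and changed by 0.08 (median difference 0.54, SD 0.41), so GSC RNA alone leaves these unexplained. Degraded RNA is argued against by a 3′ minus 5′ difference of 0.07 in this array, lower than in the other PGC arrays. For an exchange with a GSC array, 26 of 26 called germ list members were higher in it than in every GSC array. Their call counted this array as PGC, so that count decides nothing. Over all measured members, without a choice by calls, the piRNA median was 5.85 in it and 4.14 to 4.30 in the GSC arrays. The germ plasm median was 7.31 against 5.12 to 5.29, and both argue against an exchange. A biological difference between the pools of gonads was not tested and stays open, and a second sort for germ cells would remove any such RNA.

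Kidney epithelium genes were higher in PGC than in GSC, and epithelial cells of the mesonephros, which adjoins the gonad, are a candidate source, although the magnetic sort should remove cells that its antibody, which is not given, does not bind. The 7 called of 13 measured list members, with GATM at 9.26 ± 0.58 and CUBN at 8.85 ± 0.50 among them, were all higher in PGC replicate 2 than in replicate 1, by a median of 1.00 (SD over genes 0.41), while the medians of all 13 were 6.98 and 6.82. The 26 called germ list members shifted by -0.04 (SD 0.36), a difference of 1.03, but 1 array against 1 decides nothing. The germ and kidney changes of -0.96 and 0.08 in PGC replicate 3 too go against a fixed ratio. But they rest on 1 array and on members chosen by different rules, and the median of all germ plasm members was higher there. Kidney cells and expression by germ cells at a fixed ratio to germ cell genes therefore cannot be told apart. All 7 kidney members were also higher in GSC replicate 3 than in GSC replicate 1, but UMOD and PODXL, of the same list, were lower in PGC than in GSC, and PAX2 is also on the gonadal somatic list. Regulated expression by the germ cells was not tested and stays open, and sorting out cells positive for an epithelial marker of the kidney would remove such cells.

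No probe set was called at least 16-fold lower in PGC than in GSC, and GSC RNA carried into the PGC fraction may set that bound. Among called probe sets the log2 fold change ran from -2.99 to 5.34. Of 91 genes that mark GSC against blastoderm and CEF, chosen without the PGC arrays, 88 (96.7%) stayed over 1 log2 unit above background in PGC replicates 1 and 2, where they lay a median of -1.89 and at lowest -2.97 from GSC. Markers needed a GSC mean of at least 7, so the bound on the falls itself largely fixed this share. It therefore cannot decide on carried GSC RNA. Some markers were higher in PGC, such as AvBD10, at 9.66 in GSC and at 11.75 and 11.99 in PGC replicates 1 and 2. The floor of the values is argued against by 1009 probe sets that were called lower in PGC and stood at least 4 log2 units above background in GSC. Expression of these genes by the germ cells themselves was not tested and stays open.

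Other splits of the 6 arrays of a comparison into 3 and 3 are too few, at 10, for a share under 0.05. The real split gave 14071 probe sets in PGC versus blastoderm, 14544 in PGC versus CEF, 8249 in PGC versus GSC and 12744 in GSC versus CEF, and 1 split, the real one, gave as many in each. The highest other split gave 0, 0, 1 and 0. For gene lists the real splits gave 13, 17, 14 and 12, with 13, 13, 11 and 11 as the highest others, and 2, 1, 1 and 1 splits gave as many. Of 100 regroupings of the 12 arrays, 2 gave as many probe sets higher in PGC than in each other group (1802, highest other 2044), 3 as many lower (420, highest other 1364), 1 as many higher in PGC and blastoderm (910, highest other 45) and 1 as many lower in both (880, highest other 87), the real one counted each time. Most of these splits and regroupings mix cell types within a group, which widens the spread. Fewer probe set calls were thus largely assured, and the shares say little on the source of the counts. Other regroupings exceeded the first 2 counts, and whether these kept the arrays of 1 cell type together was not checked.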
